A study of Oryzias latipes with 6 samples.

How the data were processed

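Whole medaka (Oryzias latipes) embryos were profiled on single-colour oligonucleotide microarrays after exposure to silver nanocolloids (SNCs), suspensions of nanometre-sized silver particles. Per the labels, each array carried Cy5-labelled cRNA made from 1 ug of total RNA of a pool of 15 embryos, and the cRNA was made by reverse transcription with a T7-oligo dT primer and in vitro transcription. Embryos entered exposure at stage 21 and stayed in the dark for 48 h at 25 °C, in 5 mL of solution that was renewed every 24 h. There were 3 control arrays at 0 mg/L and 3 SNC-exposed arrays at 0.05 mg/L, and groups and replicate numbers were taken from the sample titles. The labels describe separate sets of embryos in wells, with 3 sets per condition in one text and 6 exposed sets in another; 3 arrays per group were analysed here. The p-values therefore measure the spread between these pools.

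Each scanner table holds, per the file headers, the pixel number and the foreground mean, SD and median intensity of 12544 spots at 635 nm, on a linear scale that ends at 65535. No background column was present, and empty spots read above 0, so the deposited intensity had not been background-corrected. Of the spots, 12000 carried 5600 medaka probes, 4832 of them in 2 copies, 736 in 3 and 32 in 4. The rest were 70 negative-control, 148 empty and 326 quality-control spots. Each deposited table of processed intensity was compared with the foreground median of the same array: every value equalled it minus the mean of the empty spots of that array, with a range of 0 for that difference. The authors' table was thus not scaled between arrays, although the titles call the samples normalized; its column medians were 187.8, 264.9 and 213.5 for the controls and 141.6, 138.6 and 183.7 for the exposed arrays. Spot-finding software and scanner are not given in the sources used here. Per the names of the scans, the control arrays were scanned at a photomultiplier gain of 600 and the exposed arrays at 550, so gain and exposure cannot be told apart on the raw scale. Normalization evens out the distribution of intensities, but other differences that ran with the gain would remain in the normalized values.

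Foreground medians were corrected by normexp with an offset of 50 on all spots, converted to log2, quantile normalized over the medaka spots and averaged over the spots of each probe (R 4.3.3, limma 3.58.1). No background flag was in the files, so a probe was kept when its mean foreground exceeded the 95th percentile of the negative-control spots on at least 3 of the 6 arrays; 3117 probes for 3097 described genes passed. Groups were compared with lmFit and eBayes on group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; a second count also required a change of at least 2-fold. Fold changes are on the normalized log2 scale with that offset and understate the change of dim probes. A probe below background on all arrays of a group has only a bound, computed as the mean of the brighter group over the mean of, per array of the dim group, the higher of the probe's own value and the lowest signal among probes above background. Such a bound takes no account of the spread between arrays. Single values were compared with exact two-sided permutation tests, for which 3 against 3 arrays cannot give a p under 0.1.

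Probe names are the product descriptions carried by the files, which are those of the array's design and can be old. They were not matched to genome positions, and no coordinates are given. The 30 gene lists, the rule for named genes and most alternatives had been fixed before the data were examined. The lists were gene symbols; because the files hold descriptions, each was rewritten as search terms in the words of the descriptions before any intensity was tested, and 2 lists were added from the array's content. The lists covered N-glycan synthesis, O-linked and mucin-type glycosylation, sialic acid and sugar-nucleotide metabolism, glycosaminoglycan synthesis, GPI-anchor synthesis, lysosomal glycan degradation, metal response, oxidative stress and glutathione, heat shock, ER stress, apoptosis and p53, cell cycle, ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, extracellular matrix, cartilage and bone, muscle, erythroid cells, blood vessels, eye, nervous system, liver with pancreas and yolk, hatching gland and chorion, skin and ionocytes, pigment cells, innate immunity, developmental signalling, proteasome and lipid synthesis. The added lists were galectins, lectins and annexins, and fucosyl, glycolipid and terminal glycosylation. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 on 1 value per description (the mean of its probes), adjusted over the 31 lists tested; camera with an estimated correlation and fry stand beside it. The blood vessel list had 3 measured genes and was not tested.

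Named genes followed a fixed rule. Among probes with a usable description, adjusted p below the threshold, no overlap between groups and signal above background on every array of a group, up to 12 per direction were taken by size; where fewer than 5 passed, the list was filled to 5 by unadjusted p, and these are given as not past the threshold. Each list could add up to 4 members with the smallest p: 4 were used for lists past the threshold and at least 2 for the others. Cyclin B1, cytochrome P450 1C1 and further probes for genes already named were looked up after values had been seen.

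The procedure was tested on simulated data with the spread of each probe on these arrays, drawn independently for each probe. Of 49 probes changed by 0.5 on the log2 scale 51% were called, of 49 changed by 1 95.9% were called, and all changed by 1.5 or 2 were called, with 10 false calls among 177. The fitted sizes averaged 0.43, 0.88, 1.33 and 1.73, since the offset compresses changes. With no change simulated, 0 probes and 0 lists were called. The shares called hold for 200 changed probes, and the adjustment is stricter where fewer probes change. On the real arrays a probe with a log2 difference of 0.81 did not pass. The simulation held no variation shared between probes. It therefore cannot give the rate of false calls, of probes or lists, where the arrays share such variation. Alternatives to the background correction, normalization, filter, variance model, value table and replicates were run; some were added after the data had been seen, as the closing text states. Figures and array summaries were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Precision is limited by the number of arrays.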

Results

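Gene expression was measured in 6 pools of whole medaka embryos, 3 kept without silver and 3 exposed to 0.05 mg/L of silver nanocolloids for 48 h from stage 21. The nanocolloids were particles of 28.4 ± 8.5 nm in mean diameter, supplied with a part of ionic silver. The title of the series names glycosylation, the attachment of sugar chains to proteins and lipids, and embryonic malformation as its subject, and the array carries many probes for glycosylation enzymes. The median foreground intensity of the medaka spots was 222.5, 300.0 and 250.75 on the control arrays and 176, 173 and 227.5 on the exposed arrays. Between 45.4% and 58.3% of the 5600 probes lay above the negative controls on each array. Arrays of one group correlated with r from 0.951 to 0.991 across probes, which are not independent replicates. Arrays of different groups correlated nearly as well, with r from 0.944 to 0.986.

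The comparison of exposed with control embryos asked which genes differed after exposure. Cytochrome P450 1A, a monooxygenase of foreign-compound metabolism that is induced through the aryl hydrocarbon receptor, was 2.94-fold lower in exposed embryos (log2 difference -1.56, SE 0.15; limma adjusted p = 0.0025). Its normalized log2 intensity was 9.61 ± 0.33 in controls and 8.06 ± 0.06 in exposed embryos (SD, n = 3), and it was lower in all 3 exposed pools. Ornithine decarboxylase antizyme 2, from the family of proteins that inhibit polyamine synthesis, was 1.55-fold lower (log2 difference -0.64, SE 0.10; adjusted p = 0.0368). An opiate receptor-like transcript was 2.25-fold higher (log2 difference 1.17, SE 0.18; adjusted p = 0.0368). The transcript of ktu (kintoun), a factor for the assembly of ciliary dynein arms, was at least 1.63-fold higher, since its probe was not above background on any control array (fitted log2 difference 0.89, SE 0.12; adjusted p = 0.0368). The proximal element-binding transcription factor gamma chain was 1.77-fold higher (log2 difference 0.83, SE 0.13; adjusted p = 0.0368), with a probe above background on 1 of 3 control arrays.

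**Figure D1:**
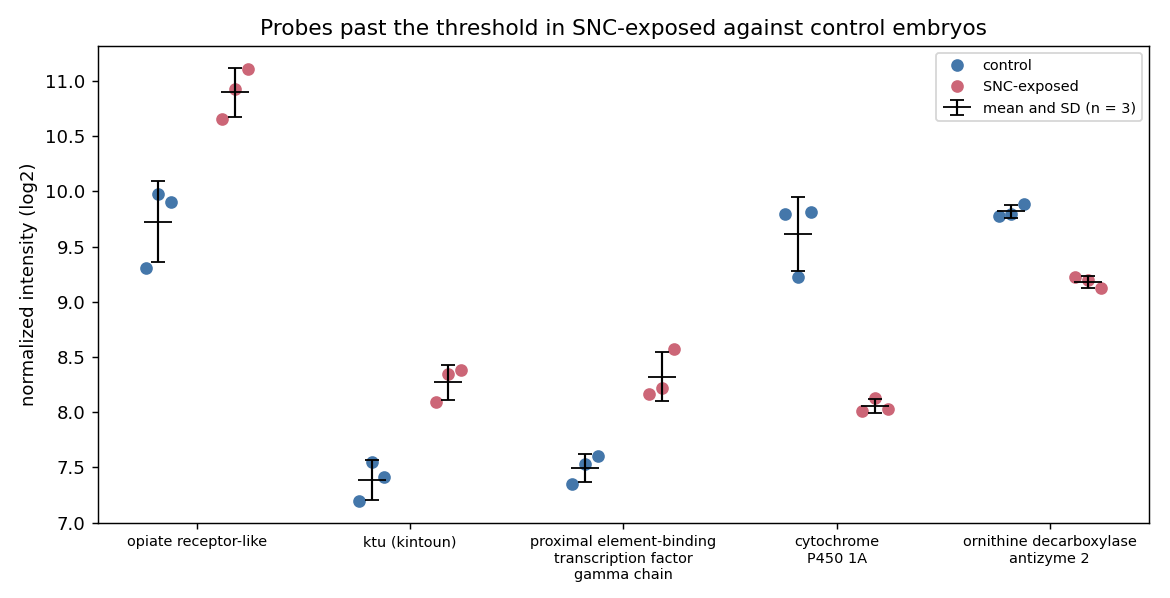
Normalized intensity (log2, vertical axis) of the 5 probes past the threshold, for each control and SNC-exposed array (points) with the group mean and SD (n = 3). Cytochrome P450 1A lay at 9.61 in controls and 8.06 in exposed embryos, and the groups did not overlap for any of the 5 probes.

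These 5 probes, 3 higher and 2 lower, were all that passed limma's test among 3117, and 2 of them changed at least 2-fold: cytochrome P450 1A and the opiate receptor-like transcript. At an unadjusted p under 0.05 there were 391 probes, 144 with higher and 247 with lower mean in exposed embryos, where 156 were expected by chance. That number was 127 without control array 1, 132 without control array 3, 118 without exposed array 3 and 1155 without exposed array 1. Of the 9 other splits of the arrays into 3 and 3, the highest gave 1258. The groups did not overlap for 462 probes (14.8%, against 10% by chance). Cytochrome P450 1A stayed past the threshold in all 22 alternatives, with an adjusted p of at most 0.0345. It was the only probe left without the filter on dim probes, with the share of probes above background as a covariate, or when any 1 control array, exposed array 2 or exposed array 3 was left out, whereas 588 probes passed without exposed array 1, 4 of the 5 among them. Median scaling left 3 probes, 1 higher and 2 lower.

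Further genes had the smallest unadjusted p in their direction without passing the threshold. The androgen-withdrawal apoptosis protein RVP1 had a log2 difference of 0.81 (SE 0.14; limma adjusted p = 0.0723). For the lysosomal-associated protein transmembrane 4A it was 0.66 (SE 0.14). Apolipoprotein E, a lipid carrier, differed by -0.59 (SE 0.11), the astacin-type protease nephrosin by -0.57 (SE 0.11) and protein arginine methyltransferase 1 by -0.61 (SE 0.13).

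Of 31 gene lists 4 passed, 2 higher and 2 lower, and 0 passed with an estimated correlation. With median scaling 6 passed, 1 higher and 5 lower, and with 75th percentile scaling 7, 1 higher and 6 lower. Genes of the cell cycle and DNA replication were lower as a group in exposed embryos. Of 25 measured genes 23 had a lower mean, and the mean log2 difference over the list was -0.21 (camera adjusted p = 4.78e-06; adjusted p = 0.796 with an estimated correlation). The list's mean relative to controls was -0.10, -0.28 and -0.25 on the exposed arrays and lay between -0.04 and 0.04 on the control arrays. No member passed over all genes tested; adjusted over the list alone, 5 were lower. These were cdc2, the mitotic cyclin-dependent kinase, with a log2 difference of -0.59 (SE 0.16), the replicative helicase subunit MCM4 with -0.56 (SE 0.15), and cell division cycle 20 homolog, an activator of the anaphase-promoting complex, with -0.39 (SE 0.11). The others were aurora kinase B with -0.35 (SE 0.11), whose probe was above background on 1 exposed array, and cyclin B1 with -0.39 (SE 0.12), named here after its value was seen. A second probe described as cdc20 differed by -0.16. With the share of probes above background as a covariate, the mean of the list was -0.14 (adjusted p = 1.33e-04; adjusted p = 0.715 with an estimated correlation).

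**Figure D2:**
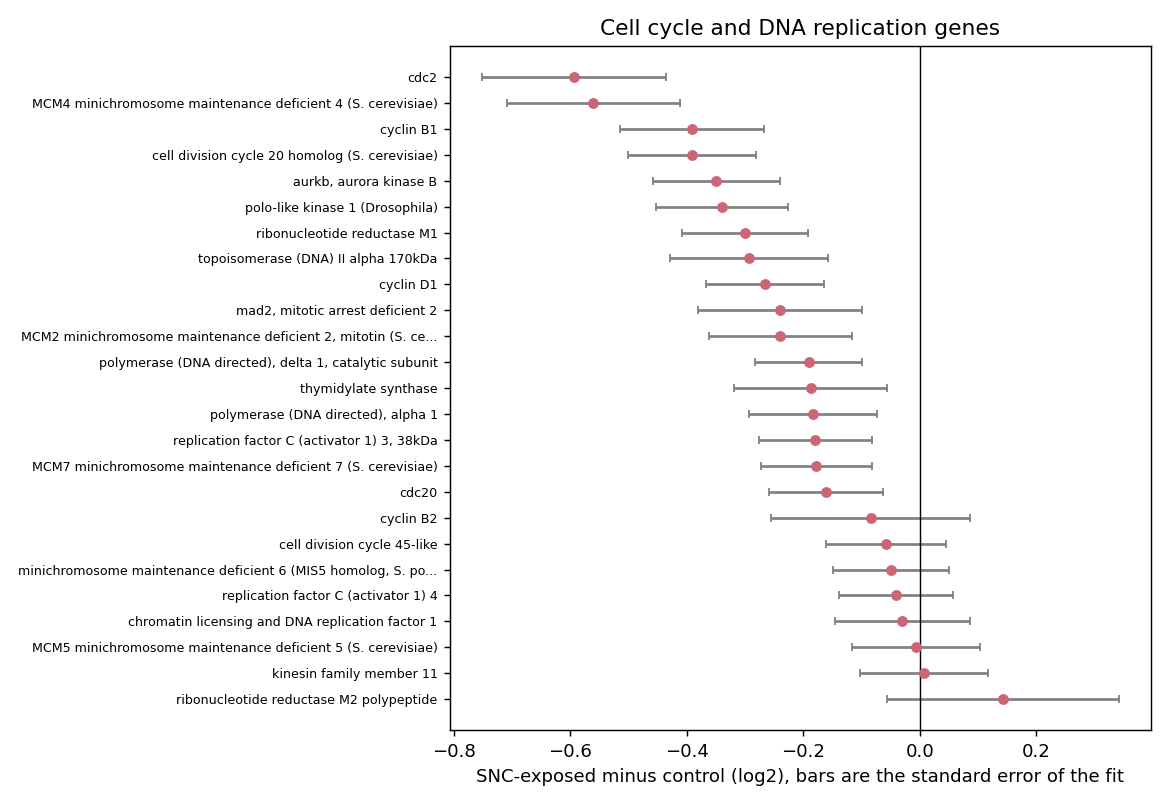
Log2 difference between exposed and control embryos (horizontal axis) for each of the 25 measured genes of the cell cycle and DNA replication list, with the standard error of the fit as bars. Values below 0 were found for 23 genes, down to -0.59 for cdc2.

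Genes of the nervous system were also lower as a group, with a mean of -0.13 over 21 genes, 15 of them negative (camera adjusted p = 0.0284; adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone 2 were lower: SOX3, a transcription factor of neural progenitors, with -0.50 (SE 0.11), and the neuronal RNA-binding ELAV-like protein 3 with -0.58 (SE 0.15), above background on 1 exposed array. The list's mean relative to controls was -0.02 on exposed array 1, within the control range of -0.03 to 0.04, and -0.22 and -0.16 on the other exposed arrays. Tubulin beta 2C had -0.38 (SE 0.13) and orthodenticle homolog 1, a forebrain regulator, -0.32 (SE 0.15). The nervous system call ended without exposed array 2 (mean -0.093, adjusted p = 0.2), without control array 2 (-0.15, adjusted p = 0.0674) and with the share of probes above background as a covariate (-0.062, adjusted p = 0.415). Skeletal and cardiac muscle genes were higher as a group, with a mean of 0.14 over 18 genes, 16 of them positive (camera adjusted p = 0.0225; adjusted p = 0.796 with an estimated correlation). Muscle actin OlMA1 had a log2 difference of 0.41 (SE 0.16), creatine kinase M 0.29 (SE 0.10), fast skeletal troponin C 0.27 (SE 0.10) and alpha-tropomyosin 0.21 (SE 0.10), and no member passed over all genes or over the list alone. All 3 exposed arrays lay above all 3 controls for the muscle list, but its mean was 0.03 with median scaling (adjusted p = 0.201), where troponin C changed sign, and 0.075 with 75th percentile scaling (adjusted p = 0.239). The muscle call also ended without control array 2 (0.17, adjusted p = 0.0535), without the filter on dim probes (0.091, adjusted p = 0.053), on the deposited values without normalization between arrays (0.089, adjusted p = 0.131) and without control array 1 and exposed array 1 together (0.13, adjusted p = 0.0711).

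Among the glycosylation lists, the one named O-linked and mucin-type glycosylation was higher in exposed embryos. It was set by enzyme families, among them N-acetylglucosaminyltransferases and galactosyltransferases, whatever sugar chains each member builds. The mean over its 35 genes was 0.12, with 28 positive (camera adjusted p = 0.0284; adjusted p = 0.796 with an estimated correlation). The groups overlapped: relative to controls the mean was 0.0081 on exposed array 1, below control array 2 at 0.06, and 0.19 and 0.15 on exposed arrays 2 and 3. Adjusted over the list alone 2 genes were higher: radical fringe, which extends O-fucose on Notch receptors, with a log2 difference of 0.57 (SE 0.12), and the N-acetylglucosaminyltransferase bGnT-5 with 0.45 (SE 0.11). The polypeptide N-acetylgalactosaminyltransferases of the list ranged from -0.06 to 0.22, and none of them passed over the list alone. One probe for O-linked mannose beta1,2-N-acetylglucosaminyltransferase had 0.47 (SE 0.14), while 2 other probes described as that enzyme had 0.05 and -0.05, the first of which turned negative with median scaling; both changed sign without exposed array 1. Lunatic fringe had -0.37 (SE 0.12) on one probe and 0.08 on another, which was below 0 with median and 75th percentile scaling. The call ended without control array 1 (mean 0.08, adjusted p = 0.0656), without control array 2 (0.15, adjusted p = 0.0535) and without exposed array 2 (0.08, adjusted p = 0.212). It also ended without the filter on dim probes (0.07, adjusted p = 0.111), with the filter on all 6 arrays (0.13, adjusted p = 0.0565) and with the share of probes above background as a covariate (0.037, adjusted p = 0.62). The mean was 0.057 with median scaling and 0.18 without exposed array 1.

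The other glycosylation lists did not pass in the main comparison. Sialic acid and sugar-nucleotide metabolism had a mean of 0.11 over 22 genes (adjusted p = 0.0899), with sialic acid synthase, above background on 1 exposed array, at -0.37 (SE 0.10). The sialyltransferase ST3Gal III, not above background on any control array, had a bound of 1.2-fold brighter in exposed embryos. That bound leaves out the spread between arrays, and the difference did not pass (limma adjusted p = 0.336). Glycosaminoglycan and proteoglycan synthesis had a mean of 0.08 over 27 genes, 23 of them positive (adjusted p = 0.122), with the xylosylprotein galactosyltransferase at 0.24 (SE 0.12) and heparan sulfate 3-O-sulfotransferase 2 at 0.21 (SE 0.10). N-glycan synthesis had 0.06 over 27 genes (adjusted p = 0.342), just below 0 with median scaling, with mannosidase alpha 2A2 at 0.27 (SE 0.11) and UDP-glucose:glycoprotein glucosyltransferase 1 at 0.30 (SE 0.13). The GPI-anchor list had 0.11 over 6 genes (adjusted p = 0.418). Over 24 alternatives it ranged from -0.05 to 0.21, with 0.01 under median scaling, 0.04 without control array 1, 0.05 without exposed array 3 and 0.21 without exposed array 1. Among its genes were dolichol phosphate-mannose synthase 2 at 0.23 (SE 0.15) and phosphatidylinositol glycan class N at 0.14 (SE 0.14), the latter negative with the covariate. The lysosomal degradation list had -0.01 over 5 genes (adjusted p = 0.98) and -0.08 with median scaling, with neuraminidase 1 at -0.26 (SE 0.10) and arylsulfatase B at 0.15 (SE 0.11). Of the lists added from the array's content, the fucosyl and glycolipid list had 0.12 over 8 genes (adjusted p = 0.329), with galactose-3-O-sulfotransferase 4 at 0.25 (SE 0.14) and ceramide glucosyltransferase at 0.19 (SE 0.10). Galectins, lectins and annexins had 0.04 over 23 genes (adjusted p = 0.427), below 0 with median scaling, with galectin-4 at 0.29 (SE 0.11) and the cation-dependent mannose-6-phosphate receptor at -0.25 (SE 0.10). With the share of probes above background as a covariate the list means were -0.02 for glycosaminoglycans, -0.05 for GPI anchors, -0.07 for the fucosyl list, -0.0035 for N-glycans and -2.57e-05 for sialic acid. Without exposed array 1 the glycosaminoglycan (0.15, adjusted p = 0.0195), sialic acid (0.18, adjusted p = 0.0297) and fucosyl lists (0.24, adjusted p = 0.0482) passed, and the glycosaminoglycan list also passed without the filter on dim probes (0.07, adjusted p = 0.0398). The glycosaminoglycan and sialic acid lists passed as well without control array 1 and exposed array 1 together (0.12 and 0.18, adjusted p = 0.0445 and 0.0192). These calls used the preset correlation of 0.01. In the main comparison the estimated correlations of the glycosaminoglycan, sialic acid and fucosyl lists were 0.54, 0.44 and 0.81. With them camera's adjusted p was 0.796 for each list. Without exposed array 2 the glycosaminoglycan, sialic acid and fucosyl means were 0.02, 0.04 and 0.04, and with median scaling 0.02, 0.05 and 0.05. Over 24 alternatives the N-glycan mean ranged from -0.0044 to 0.11. The ratio of the 3' to the 5' quality-control probe, whose targets the files do not name, was 2.69 ± 0.07 on control and 2.48 ± 0.08 on exposed arrays (n = 3, exact permutation p = 0.1, the smallest possible). The share of probes above background was 56% ± 3.56 and 51% ± 5.86 (exact permutation p = 0.2).

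**Figure D3:**
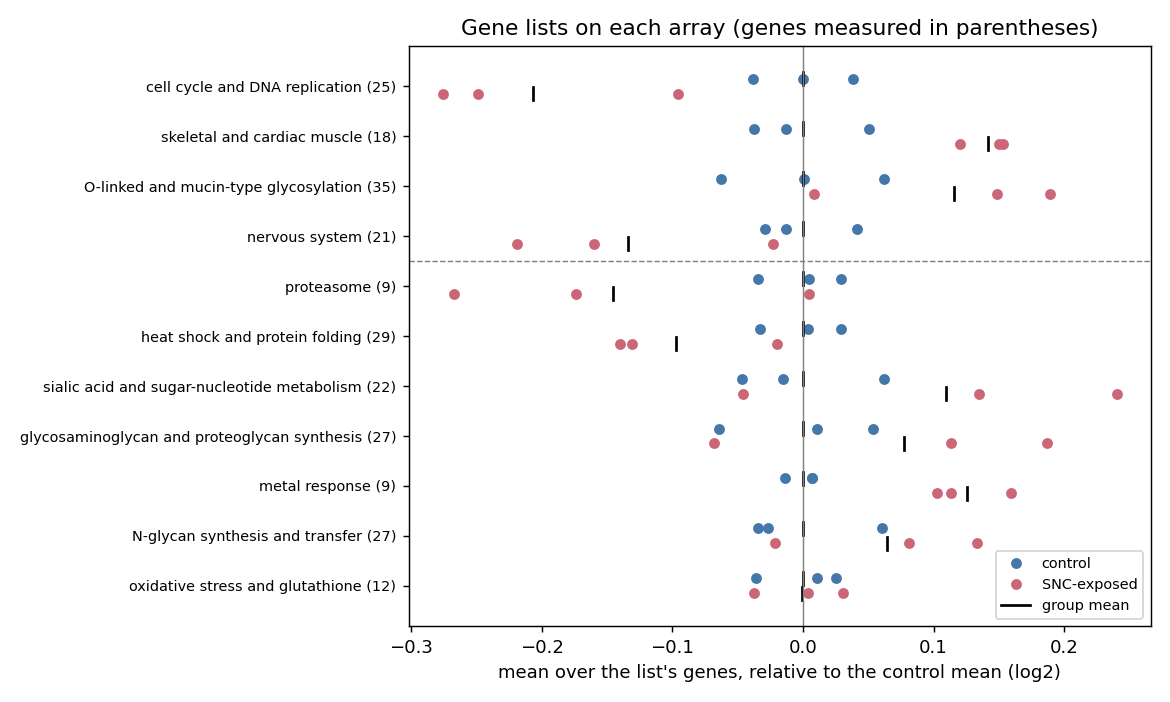
Mean over the genes of each list on each array, relative to the control mean (log2, horizontal axis), for control and SNC-exposed arrays (points) with group means (bars); the number of genes is in parentheses. The 4 lists above the dashed line passed camera's test with a preset correlation. Their group means were -0.21, 0.14, 0.12 and -0.13, and the muscle mean shrank to 0.03 with median scaling. The lists below the line are a selection. Of all 31 lists tested, drawn or not, 8 changed sign under at least 1 other scaling. Metal response and N-glycan synthesis were the ones drawn here, and the 4 that passed were not among them.

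Lists for responses to metals and to stress did not pass in the main comparison. The metal response list had a mean of 0.13 over 9 genes (adjusted p = 0.294), and all 3 exposed arrays lay above all controls, but the mean was -0.03 with median scaling. Metallothionein, the metal-binding protein, differed by 0.33 (SE 0.12; limma adjusted p = 0.34) and the ferritin middle subunit, an iron-storage protein, by 0.23 (SE 0.10), a value that was near 0 and negative with median scaling. Oxidative stress and glutathione genes had a mean of -7.73e-04 and a median of 0.0059 over 12 genes (camera direction up, adjusted p = 0.98); catalase, which degrades hydrogen peroxide, had -0.48 (SE 0.14) and sequestosome 1 0.29 (SE 0.12). Heat shock and folding genes had -0.10 over 29 genes, 21 of them negative (adjusted p = 0.0564), with the chaperonin subunit CCT5 (TCP1 subunit 5) at -0.36 (SE 0.10), and at -0.28 on a probe described as subunit epsilon, and the collagen chaperone heat shock protein 47 at -0.35 (SE 0.10), for which a second probe had 0.09. All 9 proteasome genes were negative, with a mean of -0.15 (adjusted p = 0.0564), the 26S non-ATPase subunit 11 at -0.32 (SE 0.12) and the beta 3 subunit at -0.19 (SE 0.10). The proteasome mean relative to controls was 0.0049 on exposed array 1 and -0.27 and -0.17 on the others. Both lists passed with median scaling (heat shock -0.18, proteasome -0.26, adjusted p = 0.0221 for each), with 75th percentile scaling (-0.13 and -0.21, adjusted p = 0.0191 and 0.0164) and without exposed array 1 (-0.14 and -0.22, adjusted p = 0.0379 and 0.0327). They also passed without control array 1 and exposed array 1 together (adjusted p = 0.0445 and 0.0312). Heat shock passed on the deposited values without normalization (adjusted p = 0.0378), and the proteasome without control array 3 (adjusted p = 0.0269) and with the filter on all 6 arrays (adjusted p = 0.0328). These calls used the preset correlation. With an estimated correlation, camera's adjusted p in the main comparison was 0.796 for both lists. With the share of probes above background as a covariate the means shrank to -0.05 for heat shock and -0.06 for the proteasome (adjusted p = 0.415 for each), and the proteasome had -0.09 without exposed array 2. ER stress genes had -0.01 over 11 genes (adjusted p = 0.933), with calreticulin-3 at -0.15 (SE 0.10) and calreticulin at 0.15 (SE 0.10). Apoptosis and p53 genes had 0.08 over 5 genes (adjusted p = 0.544), about 0 with median scaling, with p53 at 0.26 (SE 0.11) on one probe and 0.06 on another, and mcl1a at -0.19 (SE 0.12).

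Lists for metabolism gave no call in the main comparison. Ribosomal proteins had -0.07 over 11 genes (adjusted p = 0.418); large subunit P1 was higher when adjusted over the list alone, with 0.46 (SE 0.11), and L8 had -0.34 (SE 0.12). The ribosomal list passed as lower with median scaling (-0.29, adjusted p = 0.0221), with 75th percentile scaling (-0.24, adjusted p = 0.0164) and on the deposited values without normalization (-0.21, adjusted p = 0.0378). Its mean was -0.03 without control array 1. Oxidative phosphorylation had -0.002 over 19 genes (adjusted p = 0.948), with the ATP synthase OSC protein at -0.30 (SE 0.13) and ubiquinol-cytochrome c reductase binding protein at 0.27 (SE 0.13), the latter below 0 with median scaling. Glycolysis and hypoxia had a mean of -0.0037 and a median of 0.04 over 20 genes (camera direction up, adjusted p = 0.98); triose phosphate isomerase B was lower adjusted over the list alone, with -0.54 (SE 0.13), and phosphoglycerate kinase had 0.25 (SE 0.12). A probe described as phosphoglycerate kinase 1 had -0.08. Lipid and cholesterol synthesis had 0.0073 over 5 genes (adjusted p = 0.948), negative with every other scaling, with the fatty acid elongase 1-like gene at 0.28 (SE 0.13) and HMG-CoA reductase b at -0.29 (SE 0.16). Other probes described as HMG-CoA reductase had 0.07 and 0.05.

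Lists for other tissues of the embryo did not pass either. Liver, pancreas and yolk genes had -0.07 over 11 genes (adjusted p = 0.427), and -0.17 with 75th percentile scaling, where they passed (adjusted p = 0.049), within a range of -0.22 to -0.02 over 24 alternatives; apolipoprotein E was lower adjusted over the list alone, and apolipoprotein A-I had 0.26 (SE 0.10). Eye genes had -0.10 over 8 genes (adjusted p = 0.329). Over 24 alternatives they ranged from -0.19 with median scaling to -0.03 with the covariate, with -0.17 without exposed array 1, whose own mean was 0.06, and -0.05 without exposed array 2. Among them were the crystallin B1-like gene at -0.33 (SE 0.13) and the lens water channel MIP at -0.31 (SE 0.12). Erythroid genes had 0.11 over 7 genes (adjusted p = 0.427), below 0 with median scaling, with the blood-stem-cell factor TAL1 at -0.23 (SE 0.10) and adult alpha-type globin at 0.34 (SE 0.17). Hatching gland and chorion genes had 0.07 over 14 genes (adjusted p = 0.418), with the hatching enzyme-like protease MAHCE at -0.33 (SE 0.11) and the astacin-like MC6AST3 at 0.31 (SE 0.11). Extracellular matrix genes had 0.02 over 25 genes (adjusted p = 0.736), below 0 with median and 75th percentile scaling, with matrix metalloproteinase 14 at -0.38 (SE 0.14) and fibromodulin at -0.28 (SE 0.11). Cartilage and bone had a mean of -5.57e-04 and a median of 0.03 over 7 genes (camera direction down, adjusted p = 0.98), with matrilin 4, above background on 1 exposed array, at -0.18 (SE 0.12) and SOX9 at 0.17 (SE 0.16), the latter negative with the covariate. Skin and ionocyte genes had -0.04 over 19 genes (adjusted p = 0.427), with anterior gradient-2 at 0.37 (SE 0.14) and envoplakin at -0.25 (SE 0.12). Pigment cell genes had 0.05 over 8 genes (adjusted p = 0.51), -0.03 without exposed array 1 and 0.09 without exposed array 2, with 2 probes described as Pax7 at 0.26 (SE 0.10) and -0.30 (SE 0.13). Innate immunity had 0.02 over 14 genes (adjusted p = 0.51), below 0 with median scaling, with complement factor I at 0.34 (SE 0.10) and interferon regulatory factor 2 at -0.42 (SE 0.17). Developmental signalling (Wnt, BMP, Hedgehog and FGF) had -0.02 over 27 genes (adjusted p = 0.896), with Wnt11, above background on 2 control arrays and 1 exposed array, at -0.43 (SE 0.14) and a Smad4-like gene at 0.30 (SE 0.13). Other Smad4 probes had 0.06 and 0.03. With the share of probes above background as a covariate 12 of the 31 list means changed sign, among them hatching gland and chorion (-0.02), skin and ionocytes (0.0063), apoptosis and p53 (-0.02) and oxidative phosphorylation (0.08). Without exposed array 1, the means of 14 of 26 lists that had not passed grew by over 1.5 times and 4 changed sign. Without exposed array 2, 9 of 27 shrank by over 1.5 times, 6 grew as much and 3 changed sign. Control arrays mattered as well: without control array 1, 9 of 26 shrank by over 1.5 times, 4 grew as much and 4 changed sign. Without control array 2, 3 of 27 shrank, 10 grew and 1 changed sign. No list passed with fry, whose lowest adjusted p was 0.148, and no list member passed over all genes. Probes above background on 2 arrays of a group were those of the xylosylprotein galactosyltransferase and the first Pax7 in controls, heat shock protein 47, matrix metalloproteinase 14, TAL1 and the second Pax7 in exposed embryos, and sequestosome 1 in both.

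The raw brightness of the arrays was compared last. The median foreground averaged 257.75 ± 39.2 on control and 192.2 ± 30.6 on exposed arrays (SD, n = 3), a ratio of 0.746 (exact two-sided permutation p = 0.2). Because the exposed arrays were scanned at a gain of 550 and the controls at 600, the raw level is not a measure of RNA, and gain and group cannot be told apart.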

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

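Signals outside the medaka probes were compared between groups, a check chosen after the arrays had been seen. The mean foreground of the empty spots was 42.33 on exposed array 3, above the highest control value of 35.53; the other exposed arrays read 32.4 and 33.44. The quality-control probe family with 200 spots per array, whose target the files do not name, was brighter on all exposed arrays relative to the array's median medaka spot after subtraction of the empty level: 0.228 ± 0.018 against 0.195 ± 0.017 on controls (n = 3), with a highest control value of 0.207. The other 6 quality-control families overlapped between groups. No biological explanation was tested for these readings.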

How the results depend on the processing

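The tests chosen after the data had been seen used the foreground mean, the value table without normalization, the filter on empty spots, the share of probes above background as a covariate, and the joint omission of control 1 and SNC-exposed 1. Cytochrome P450 1A passed in all 22 alternatives run for probes, with log2 differences from -1.76 to -1.44 and adjusted p from 1.04e-15 to 0.0345. Over the 10 genes named outside the lists, 157 of 214 values kept direction and side of the threshold, 39 lost the call, 18 gained one and 0 reversed. None of the 75 named members of lists passed over all genes in the main comparison, so none could lose a call. Of their 1624 values 1528 kept direction and stayed short of the threshold, 82 gained a call and 14 reversed. The cause of the changes below was not tested; settings that leave out arrays rest on fewer of them, and those without the filter test more probes. Log2 differences and list means without normalization are given relative to the median of all probes, which was -0.50 there. Probe counts and p-values in that setting were computed before this shift was taken out.

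Against 5 probes, 2 of them at least 2-fold, 4 lists and 5 named genes, the counts changed by more than 1.5 times as follows. Median scaling gave 3 probes, 1 at least 2-fold and 3 named genes, and 75th percentile scaling gave 1 probe at least 2-fold and 7 lists. The normalized value table gave 4 probes at least 2-fold. Without the filter on dim probes, and with the filter on empty spots, which both kept 5600 probes, 1 probe passed, 1 at least 2-fold and 1 named gene. The filter on all 6 arrays left 3 probes and 3 named genes. An estimated correlation gave 0 lists. The foreground mean gave 2 probes, 1 at least 2-fold and 2 named genes. The table without normalization gave 1019 probes (1 higher, 1018 lower), 59 at least 2-fold and 3 named genes. These probe counts are not relative to the median of all probes. They include the lower raw brightness of the exposed arrays, which ran with the gain. The covariate gave 1 probe, 1 at least 2-fold, 2 lists and 1 named gene. Control 1 and SNC-exposed 1 left out gave 54 probes and 7 lists. Leaving out 1 array gave from 1 to 588 probes, 1 to 2 at least 2-fold, 1 to 9 lists and 1 to 4 named genes; 588 came without SNC-exposed 1. Smaller changes were 4 probes with 75th percentile scaling (2 higher, 2 lower) and with trend and robust variance (3 higher, 1 lower), each with 4 named genes, 3 at least 2-fold with an offset of 16, 3 lists without the filter and above the empty spots, 5 without normalization and 6 with median scaling.

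The O-linked mean was 0.0672 without the filter and above the empty spots, 0.1275 with the filter on all 6 arrays, 0.0373 with the covariate and 0.1154 with an estimated correlation, where adjusted p was 0.796. The muscle mean was 0.0275 with median scaling, 0.0746 with 75th percentile scaling, 0.0907 without the filter and above the empty spots, 0.0891 without normalization, 0.1301 without control 1 and SNC-exposed 1, and 0.1413 with an estimated correlation. The nervous system mean was -0.0622 with the covariate and -0.1338 with an estimated correlation; the cell cycle mean lost its call with an estimated correlation alone (-0.2066). Leaving out 1 array gave 0.0795 to 0.1757 for O-linked, 0.1202 to 0.1670 for muscle, -0.1961 to -0.0927 for nervous system and -0.2594 to -0.1743 for cell cycle genes.

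No value that changed sign passed the threshold. With median scaling these were -0.0051 for the ferritin middle subunit, -0.0070 for ubiquinol-cytochrome c reductase binding protein, -0.0146 for fast troponin C, -0.1877 for lunatic fringe homolog and -0.0244 for protein O-linked mannose beta1,2-N-acetylglucosaminyltransferase. Lunatic fringe homolog had -0.1406 with 75th percentile scaling, -0.0957 without normalization and -0.0245 without control 1 and SNC-exposed 1. With the covariate, phosphatidylinositol glycan class N had -0.0315 and SOX9 -0.0800. Leaving out 1 array gave -0.0089 to 0.1278 for the O-linked mannose enzyme and -0.1711 to 0.0870 for the probe described as its form 1, which had 0.0425 without control 1 and SNC-exposed 1.

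With the replicate number as a replicate block, 19 probes passed (9 higher, 10 lower), against 5. The numbers did not pair the arrays: deviations of same-numbered arrays correlated across probes with r of 0.57, 0.15 and -0.09, and control 2 correlated best with SNC-exposed 3 (r = 0.68). Probes near background limit what these arrays measure.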

Other observations

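A second gene of the cytochrome P450 1 family was measured beside cytochrome P450 1A. One probe for cytochrome P450 1C1, chosen after the result for 1A was seen, had a log2 difference of 0.20 (SE 0.10), with all 3 exposed arrays above all 3 controls and limma adjusted p = 0.424. Its difference stayed above 0 in the 22 alternatives. The other probe for that gene was not above background on any array. Within the glycosylation lists, 64 probes designed on predicted transcripts had a mean of 0.13 (SE between arrays 0.11), and 53 of them were positive. The 63 probes of other origin had 0.06 (SE 0.05), with 42 positive, and 25 probes on predicted transcripts outside these lists also had 0.06 (SE 0.05), with 19 positive. For the O-linked list alone, 25 probes on predicted transcripts had 0.13 (SE 0.11) and 13 others 0.12 (SE 0.04).

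Tests written only after the result was seen were those of intensity, of single spots, of scanner gain, of embryo stage and of probe source in the O-linked list alone; the covariate was also added after the data had been seen. The 3 patterns weighed are the lower cytochrome P450 1A, the lower cell cycle list and the higher glycosylation lists. Scan gain followed group, and the 3' to 5' quality-control ratio was lower on every exposed array than on every control array. It was 2.43, 2.44 and 2.57 on exposed arrays and 2.62, 2.69 and 2.76 on controls. In none of the 3 patterns can exposure be told apart from a processing difference that ran with the groups.

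For cytochrome P450 1A, a defect of 1 spot is argued against by its 2 spots, whose log2 differences were -1.71 and -1.41. In the normalized values, probes of that brightness did not fall with it: the 200 nearest in mean expression had a median of 0.03. Quantile normalization evens out shifts of that kind. The check therefore cannot speak about an effect of the scanner gain. The lowest of these neighbours had -0.62, but cytochrome P450 1A had itself been picked for its large fall. Lower expression of the whole cytochrome P450 1 class stays open: the 2 probes for 1C1 had a mean of 0.042, but 1 of them was not above background on any array, which voids that test. The 0.20 of the measured probe alone, singled out after that mean was seen, is given as a value and not as a test. What also stays open is an effect of silver on cytochrome P450 1A itself, as a hypothesis.

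For the cell cycle list, 0 of 10000 random lists matched on mean expression had a mean as low (percentile 0). The matched lists averaged -0.0019, so genes of like brightness showed no such shift in the normalized values. The percentile is no further support for the list. Quantile normalization evens out shifts with intensity, camera had already picked the list against the other genes, and random lists lack its correlation between genes. With the share of probes above background as a covariate the mean went from -0.21 to -0.14. In that fit camera's adjusted p was 1.33e-04 at the preset correlation and 0.715 with an estimated correlation. An array axis present in both groups is therefore not excluded as the whole cause. More advanced embryos, with fewer dividing cells, remain a possible explanation: eye lens, erythroid and pigment genes, which would then be higher, had a mean of 0.02 (0.0176, SE between arrays 0.039) over 23 genes. That pool does not decide, since its lists moved in different directions: eye -0.10, erythroid 0.11 and pigment 0.05. The muscle list, with a mean of 0.14, was not part of it. An effect of silver on division stays open as well.

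For the glycosylation lists, the O-linked list lay at percentile 99.96 of the matched random lists. Those averaged 0.0072, so genes of like brightness showed no such shift in the normalized values. The percentile is no further support here either, for the reasons given for the cell cycle list. An array axis present in both groups may account for much of the higher O-linked mean. With the share of probes above background as a covariate, that mean went from 0.12 to 0.04 (0.0373, camera adjusted p = 0.62). A covariate that leans towards 1 group can also take up part of an exposure effect. The source of the probe is argued against for the O-linked list, whose members outside the panel of predicted transcripts had 0.1205 (SE 0.036); over the glycosylation lists together it remains open (0.0645, SE 0.0457). An effect of exposure on these enzymes cannot be excluded either.

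The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5 probes and the highest other 410; these 2 splits, the real one included, were those with at least 5. The split with 410 set control arrays 1 and 3 with exposed array 1 against the rest and points to a structure of the samples that crosses the groups. For probes changed at least 2-fold, the real split called 2 and the highest other 0, so that 1 split, the real one, reached 2. For gene lists, the real split called 4, the highest other 7, and 5 splits, the real one included, called at least 4.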
